A study of Pleurodeles waltl with 14 samples.

How the data were processed

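Brain or head tissue of Pleurodeles waltl was dissociated with papain for 30 min, per the labels' protocols. Cells of each stage were labelled with 4 multiplexing oligos and loaded for droplet capture with a target of 5000 to 8000 recovered cells. For the 14 libraries the submitters' processing notes name Salmon 1.6.0, alevin and Seurat, with no role or setting stated. The genome build, the annotation and the steps of tag assignment are not given in the sources used here.

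The analysed file was the list of multiplexing oligos that the authors deposited for the whole series. Its name calls it a default reference, so its sequences were not shown to have been chosen for this study. Per the file headers the list gives, for each oligo, its name, the read and position that carry the tag, the tag sequence and the feature class. All of these are text. The list has no counts and no depth, so no interval, detection limit, replicate error or test between libraries could be formed, and replicates were not averaged. The tables used here included no transcript or tag counts. A gene table of the organism without sequence was at hand and was not used, and the search for tags in transcripts that had been planned was not run for lack of transcript sequence. By the rule fixed before the data were examined, genes were to be named only from that search, so none is named.

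Libraries were grouped by stage and library kind from their titles, and the tags of each stage were read from the descriptions of the tag libraries. Distances between tags were computed with Python 3.11.15 and NumPy 2.4.6, and the heat map was drawn with Matplotlib 3.10.9. The main distance was the Hamming distance. The minimum over all pairs was compared with 100000 sets of 12 sequences drawn with equal base frequencies (seed 1), as the one-sided share of sets with a minimum at least as large, with 1 added to both counts. The minimum among the 4 tags of a stage was compared by exact enumeration with all 495 sets of 4 tags. A share under 0.05 was the threshold. Alternatives were the Levenshtein distance, which also counts insertions and deletions, the inclusion of reverse complements, the first 10 bases only, and shifts of 1 or 2 bases. The distance functions were tested on simulated sequences with known answers, and all 6 cases gave the known value. SDs over tags or pairs describe the spread of the list and are not experimental error, and pairs that share a tag are not independent.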

Results

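The series profiled single cells of Pleurodeles waltl, the Iberian ribbed newt, a salamander, at 4 developmental stages. It comprised 14 droplet-based libraries, of which 7 held transcripts and 7 held multiplexing tags. Stage 30 had 1 library of each kind, and stages 33, 50 and 53 each had 2 of each kind. The tissue label was head at stages 30 and 33 and telencephalon, the anterior part of the forebrain, at stages 50 and 53, so stage and tissue changed together between the early and the late libraries. The series title gave a range of stages 30 to 53 and the design text a range of 30 to 55, while the latest stage among these 14 libraries was 53.

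The series title states the question as how layering of the cortex develops across tetrapods. The data analysed here were a default list of multiplexing oligos, which serve to tell pooled cells apart, and they held no value measured in a library. The labels named 5 of the 12 listed tags, for stages 50 and 53, so use of the other 7 in this series was not shown. Read depth, cell numbers, gene expression, cell types and differences between stages or tissues were not analysed here. The comparisons below therefore concern tag sequences alone.

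A multiplexing oligo is a lipid-anchored DNA molecule that labels the cells of one pool before all pools are loaded together, so that each droplet can be assigned to a pool by its tag reads. The list held 12 oligos, CMO301 to CMO312, each with a tag of 15 bases, and all 12 sequences were different. All 12 tags were placed at the 5′ start of read 2. The list gives no genome position for the tags, and their match to the newt genome was not analysed here.

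The labels named the tags of the stage 50 and stage 53 tag libraries and not those of stages 30 and 33. At stage 50 the labels of both tag libraries named CMO308 (CGGATTCCACATCAT), CMO309 (GTTGATCTATAACAG), CMO310 (GCAGGAGGTATCAAT) and CMO311 (GAATCGTGATTCTTC). At stage 53 the labels of both named CMO309, CMO310, CMO311 and CMO312 (ACATGGTCAACGCTG). Tag reads were not available to check this. Of the 5 tags named at either stage, 3 were named at both. CMO308 was named for stage 50 alone and CMO312 for stage 53 alone among these libraries, and these tags differed from each other at 12 bases. The labels did not say what each tag marked, such as an animal or a dissected piece.

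The first comparison asked how many sequencing errors separate one tag from another. Over the 66 pairs of tags, the Hamming distance, which is the number of positions with different bases, was 11.7 ± 1.70 (mean ± SD over pairs) and ranged from 7 to 15. The closest pair was CMO303 (CCGTCGTCCAAGCAT) and CMO312, at 7 bases. CMO303 and CMO308 differed at 8 bases, as did CMO301 (ATGAGGAATTCCTGC) and CMO306 (AAGATGAGGTCTGTG). CMO305 (CGCGATATGGTCGGA) and CMO312 differed at 15 bases, that is, at every position. A minimum of 7 means that a read with up to 3 substitutions lies nearer to its own tag than to any other in the list. This tolerance is for substitutions only. With insertions and deletions also counted (Levenshtein distance), the minimum was 6, between CMO303 and CMO308, which leaves a tolerance of 2 errors. Of 100000 sets of 12 uniformly random sequences of 15 bases, 75829 had a minimum Hamming distance of at least 7. That is a one-sided share of 0.758, and the median minimum of these sets was 7. The minimum Hamming distance of the list was thus not larger than random sequences of this number and length give. This holds for the minimum only. The mean distance of 11.7 lay above the 11.25 expected of random bases, and it is taken up below with base use.

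The second comparison asked how far apart the tags pooled at one stage lay. Among the 4 stage 50 tags the distance was 11.7 ± 1.86 (mean ± SD over 6 pairs), with a minimum of 9 between CMO308 and CMO309. Among the 4 stage 53 tags it was 11.0 ± 1.26 (6 pairs), with a minimum of 9 between CMO311 and CMO312. Both minima exceeded that of the full list, since each pair closer than 9 included CMO301 or CMO303, which the labels named for neither stage. By exact enumeration, 371 of the 495 possible sets of 4 tags from the list, or 74.9%, had a minimum of at least 9, and the minima of all sets ranged from 7 to 12. The tag sets of the stages were not set apart from the other sets of 4 by this measure.

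**Figure D1:**
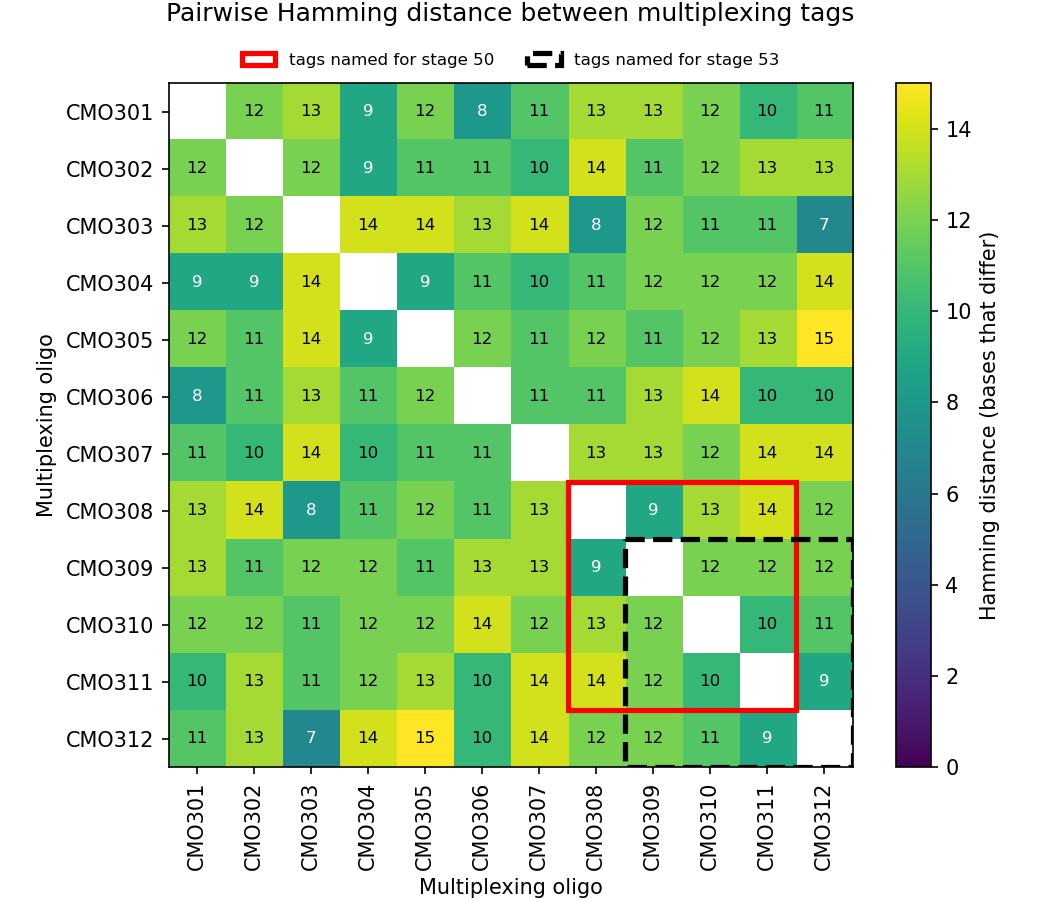
Heat map of the Hamming distance (number of differing bases, printed in each cell and coloured from 0 to 15) between the multiplexing tags CMO301 to CMO312, which are on both axes; the solid red box encloses the tags named for stage 50 and the dashed black box those named for stage 53. The smallest distance in the list, 7 between CMO303 and CMO312, lies outside both boxes, and the smallest within each box is 9.

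The GC content of the tags was 47.2% ± 8.74 (mean ± SD, 12 tags). It was lowest, at 33.3%, in CMO304 (AACGTTAATCACTCA) and CMO309, and highest, at 60.0%, in CMO303 and CMO305. Among the tags named at stages 50 and 53, CMO309 had 33.3%, CMO311 had 40.0%, CMO308 and CMO310 each had 46.7%, and CMO312 had 53.3%. The longest run of a single repeated base was 2 in each of the 12 tags.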

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

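The minimum distance in the list was 6 by Levenshtein distance, 4 over the first 10 bases and 7 with shifts of 1 or 2 bases. In none of these 3 settings did it pass the threshold against random sets (shares of 0.833, 0.797 and 0.4996), and it stayed at or above their median. With reverse complements included it was 6, below the median of 7 in random sets, with a share of 0.903. The stage 50 tags had a minimum of 8 by Levenshtein distance and 7 over the first 10 bases, where 66.5% and 26.3% of the 495 sets of 4 were at least as far apart. The stage 53 tags had a minimum of 8 by Levenshtein distance. Over their first 10 bases it was 5, below the median of 6 over all sets, and 82.0% of sets were at least as far apart; the cause was not tested. The mean GC content was 45.8% over the first 10 bases, within 1 SD of the value over the full tags. The search for tags in transcripts, exact, with 1 substitution or on 1 strand, was not run. No paired analysis was possible because the list holds no value per library. For the same reason leaving out a replicate could not be tried. The list has no read depth that would limit these values.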

Other observations

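The tests of runs of a repeated base and of complementary stretches were chosen only after the sequences had been seen, as were their alternative backgrounds. Values adjusted by Benjamini-Hochberg are over the 5 tests of the list's sequences.

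Bases were spread evenly over the positions. All 4 bases occurred at 14 of the 15 positions. The exception was position 1, counted from the 5′ end, where A occurred in 5 tags, C in 4, G in 3 and T in none. No base was shared by more than 5 tags at any position. The summed squared deviation from equal base use was 80, against a median of 134 in random sets, and a share of 0.0128 of random sets were as even (adjusted 0.032). This test, set before its result was seen, argues against independent random bases as the source of the list. For a given number of tags, this sum fixes the mean Hamming distance, which was 11.7 against 11.25 expected of random bases. Evenness of bases and mean distance are therefore not separate evidence. The test cannot tell a choice for base balance during sequencing from a choice for distance between tags, and neither was tested. The minimum distance of 7 had a share of 0.758 (adjusted 0.758), so the minimum alone does not tell the list from random bases.

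No tag held the same base more than 2 times in a row, while the median longest run in random sets of 12 tags was 4. Of 100000 random sets, 13 had a longest run as short (share 0.00014, adjusted 0.0007). Against tags shuffled within their own base composition the share was 0.00131. Because the test was prompted by the sequences themselves, these shares describe the list and are not independent evidence, and a design rule against such runs is only a candidate explanation.

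CMO301 (ATGAGGAATTCCTGC) held a stretch of 10 bases, AGGAATTCCT at positions 4 to 13, that equals its own reverse complement. Copies of this oligo could in principle pair with each other there, which was not tested. The stretch contains the recognition site of EcoRI. The test took the longest stretch whose reverse complement lies anywhere in the same tag, a wider measure that also counts separated stretches. By this measure the longest stretch of the list was 10 and the median over shuffled sets was 6, and a share of 0.0704 of these sets reached 10 (adjusted 0.117), with 0.0687 for random sequences, so base composition and chance are not excluded. CMO301 was not among the tags named for stages 50 and 53. Between different tags the longest complementary stretch was 6 bases and occurred in 2 pairs. TCCTGC of CMO301 faces GCAGGA of CMO310, and AATCAC of CMO304 faces GTGATT of CMO311. Here 0.745 of shuffled sets had one as long (adjusted 0.758), and 0.721 of random sets.

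The labels give the stage 50 and stage 53 pools 3 tags in common, CMO309, CMO310 and CMO311. Each of these stages has its own tag libraries, so the library gives the stage of a tag read. By its sequence alone, a read of a shared tag could not be assigned to a stage. In contrast, CMO308 is named for stage 50 and not 53, and CMO312 for stage 53 and not 50. Whether any tag reads crossed between libraries was not analysed here, and the tags of stages 30 and 33 are not named in the labels used.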
